A study of Mus musculus with 6 samples.

How the data were processed

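Primary hepatocytes of C57BL/6 mice were perfused, cultured, infected overnight with adenovirus and lysed for total RNA, per the labels' protocols. Libraries of 3 beta-Gal and 3 HuR samples were sequenced on a NovaSeq 6000, per the series' design text. Groups and replicate numbers were taken from the sample titles. Whether libraries were strand-specific and how rRNA was removed or mRNA selected is not given in the sources used here.

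The deposited table gives FPKM for 54118 gene models in 6 columns, with coordinates, gene length and biotype, 317 of them models without a name. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.16.1 were used with the build GRCm38.p6, with no role or order given. FPKM times gene length was a whole multiple of 1 step in every library for 100% of values (tolerance 0.001), so the whole reads behind the deposited FPKM could be computed. They sum to 15413306 to 17108184 per library. The library totals used by the authors in the FPKM equal median-of-ratios size factors over 15739 genes times a common total, to within a relative difference of 1.12e-13, so values are scaled between libraries and do not depend on the reads of Elavl1 itself. For a gene model of 1 kb, 1 read is worth 0.057 to 0.066 FPKM, and 3 reads, taken as the floor, 0.172 to 0.199 FPKM. Intervals and floors cover counting error only.

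The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a pseudocount of 1, a mean-variance trend, Benjamini-Hochberg adjustment and a two-sided threshold of 0.05. It covered genes with FPKM of at least 1 in at least 3 of the 6 libraries. The group was the only term. Fold changes are on the log2(FPKM + 1) scale. Since the unit is FPKM, no count model was the main test. The step was tested on simulated data for HuR versus beta-Gal (11044 genes, 10854 of them unchanged, with the same dispersion for all). There 23.4% of genes changed 1.25-fold, 79.6% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold were called with the right sign. Of the calls, 6.49% were false. Far fewer genes change in the simulation than pass in the data, so these rates may not hold for the real comparison.

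The design, the 33 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera (preset correlation 0.01, adjusted over the 32 lists with a tested member), with an estimated correlation, with fry and with a rank test. Camera called 12 lists (9 up, 3 down), the estimated correlation 0, fry 23, fry in either direction 31 and the rank test 11. Fry asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. Named genes were Elavl1, the 12 largest positive and 12 largest negative differences among called protein-coding genes with a mean FPKM of at least 2 and no overlap between groups, and in each list up to 4 called members with the smallest adjusted p (with no call, the most abundant). No gene with a clone name had to be skipped. Some genes that the rule names are not reported. Reported HuR targets and markers of other cell types could be named whatever their p. Shares of reads were compared with an exact permutation test, whose smallest p is 0.1.

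Alternatives were pseudocounts of 0.1 and 0.5, 3 other filters, TPM scaling, median centring, quantile normalization, 2 other variance models, the replicate number as a block, limma voom on the recovered reads, protein-coding genes only and each library left out. An alternative planned for raw counts was not run, since the table holds FPKM. Gene neighbours, transcript GC content and 3' UTRs used GENCODE M21 on GRCm38 and the coordinates of the table. Of the gene models, 53620 (99.1%) were found in it by identifier, 97.1% of them with the same coordinates. A gene counted as an expressed neighbour at a mean FPKM of at least 5. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.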

Results

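Primary hepatocytes, the main cell type of the liver, were isolated from C57BL/6 mice and infected overnight with an adenovirus for HuR or with a control adenovirus for beta-galactosidase (beta-Gal). HuR is an RNA-binding protein, encoded by Elavl1, that binds AU-rich and U-rich stretches of mRNA. RNA of 3 beta-Gal and 3 HuR samples was sequenced, and the question was which transcripts differ when HuR is overexpressed. The values are FPKM (reads scaled by gene model length and library size) for 54118 gene models, placed on the mouse build GRCm38. The whole reads behind them came to between 15413306 and 17108184 per library. Nothing in the labels says that the 3 samples of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

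Elavl1 separated the groups in every library. Its FPKM was 5.45, 5.91 and 5.62 in the beta-Gal libraries and 2434, 1662 and 1709 in the HuR libraries. The means were 5.66 ± 0.233 and 1935 ± 433 (SD, n = 3 each), a 342-fold ratio and a log2 difference of 8.16 (SE 0.14, limma adjusted p = 1.16e-06). These values rest on 943 to 1068 reads per beta-Gal library and on 276216 to 379669 per HuR library, where Elavl1 took 1.75 to 2.39% of all reads. The gene (ENSMUSG00000040028) lies on chromosome 8 from 4285382 to 4325413, on the minus strand, with an exon model of 10363 bp. Reads of the endogenous gene and of the virus cannot be separated in this table, and a delivered coding sequence shorter than the model would have its FPKM understated.

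**Figure D1:**
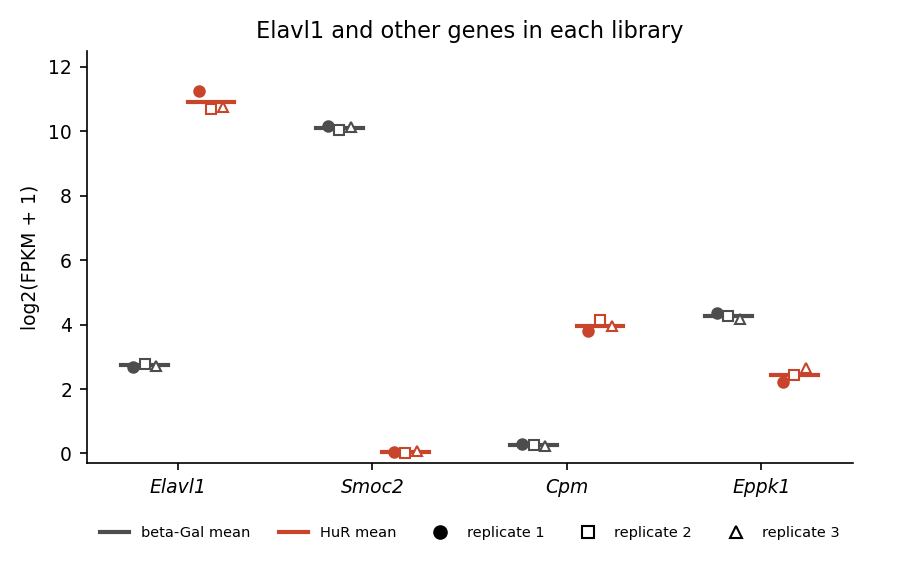
Level of 4 genes in each library on the log2(FPKM + 1) scale, with points for the 3 beta-Gal and 3 HuR replicates and a line for each group's mean. Elavl1 and Cpm lie higher in all 3 HuR libraries, and Smoc2 and Eppk1 lie lower in all 3.

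HuR libraries differed from beta-Gal libraries across much of the transcriptome, mostly by small amounts. Of 11281 genes tested, 5137 passed an adjusted p of 0.05 (limma on log2(FPKM + 1)), 2334 of them higher and 2803 lower in HuR. The median absolute log2 difference among them was 0.40. Only 415 also differed at least 2-fold, 297 higher and 118 lower. The groups did not overlap for 6554 genes (58.1%), where chance gives 10%. Among 9696 protein-coding genes, 2024 were higher and 2661 lower. Under TPM scaling the count of higher genes dropped to 1543, 29.3% of the calls against 45.4% here, with the median of all genes at -0.11 on the log2 scale. The medians and counts of gene lists given below under TPM scaling carry this shift of all genes. Fold changes on the log2(FPKM + 1) scale understate those of low genes.

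The largest fall was that of Smoc2, a secreted calcium-binding matrix protein, on chromosome 17 from 14279506 to 14404790. Its FPKM was 1105 ± 41.8 in beta-Gal and 0.023 ± 0.023 in HuR libraries (SD, n = 3 each), with a log2 difference of -10.08 (SE 0.04, adjusted p = 2.92e-10). The reads numbered 160136 in the 3 beta-Gal libraries and 3 in the 3 HuR libraries, a ratio of 49480 with an exact 95% interval of 16930 to 239900 that covers counting error only. Smoc2 was the only call below -2. Among protein-coding genes with a mean FPKM of at least 2 and no overlap between groups, the next largest falls were those of Eppk1 (epiplakin, a cytolinker, 18.3 ± 1.22 to 4.44 ± 0.792 FPKM), Heatr3, Slc35g1 and Cse1l, a nuclear export receptor, at log2 differences of -1.83, -1.75, -1.66 and -1.63. Nbeal1 fell by 1.61, and so did Chac1, a glutathione-degrading enzyme induced by amino acid stress. Chuk, a kinase of the NF-kB pathway, fell from 38.0 ± 1.07 to 12.1 ± 1.46 FPKM. Stag2, a cohesin subunit, fell from 10.4 ± 0.478 to 2.82 ± 0.119 FPKM. Faf1, Slc33a1 and Nt5dc1 fell by 1.49, 1.45 and 1.43 on the log2 scale. The adjusted p of these 11 genes other than Smoc2 was at most 1.48e-04.

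Among the same kind of genes, the largest rise after Elavl1 was that of Cpm, a membrane carboxypeptidase, from 0.197 ± 0.032 to 14.7 ± 1.71 FPKM (log2 difference 3.71, adjusted p = 5.03e-06). It faces Mdm2 at a distance of 1523 bp, and Mdm2 rose from 32.7 ± 1.07 to 113 ± 25.1 FPKM. Gzmm, Ccdc154, Avil and Ubap1l rose from under 0.3 FPKM to 9.37, 7.17, 6.95 and 6.77 FPKM. Each of these 4 starts within 10 kb of the end of an expressed gene on the same strand. The gaps were 622 bp to Cdc34, 357 bp to Clcn7, 734 bp to Ctdsp2 and 1398 bp to Pdcd7, and Avil also overlaps an expressed gene. Among the genes that fell, Heatr3 lies 2745 bp after Cnep1r1 and Cse1l lies 7988 bp after Arfgef2. Plscr2 rose from 1.14 ± 0.164 to 17.4 ± 12.1 FPKM and lies 3324 bp after Plscr1, its HuR values being 31.4, 10.2 and 10.7 FPKM, highest in replicate 1. The mitochondrial gene mt-Nd4l rose from 68.5 ± 22.5 to 392 ± 24.0 FPKM. It is 297 bp long and overlaps the start of mt-Nd4, which rose by 0.24 on the log2 scale, so reads of the overlap are uncertain. Cxcl2, a chemokine, Egr1, an early response transcription factor, and Lif, a cytokine, rose by 3.50, 2.72 and 2.72 on the log2 scale. Their levels were highest in HuR replicate 1, at 382 FPKM against 44.2 and 44.5 for Cxcl2 and 22.4 against 8.95 and 7.77 for Lif.

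Most tested genes of the cell cycle and p53 lists rose. In the cell cycle list, 21 of 29 tested members rose and none fell (23 and 0 when adjusted over the list alone), with a median log2 difference of 0.35 (camera adjusted p = 4.24e-07, 0.463 with an estimated correlation). Mcm7 and Mcm5, parts of the replicative helicase, rose from 10.5 ± 0.272 to 23.8 ± 0.315 FPKM and from 2.44 ± 0.083 to 5.04 ± 0.156 FPKM. The cell cycle inhibitor Cdkn1a, which also belongs to the p53 list, rose from 91.8 ± 2.27 to 244 ± 19.6 FPKM. Of 34 p53 targets and apoptosis regulators, 23 rose and 3 fell (the same counts adjusted over the list alone, median 0.58, camera adjusted p = 5.26e-07, 0.463 with an estimated correlation). The death receptor Fas rose from 5.25 ± 0.405 to 19.5 ± 1.17 FPKM, and Zmat3 rose from 5.45 ± 0.104 to 11.3 ± 0.430. The caspase inhibitor Xiap fell from 12.8 ± 0.322 to 5.31 ± 0.056 FPKM. None of the 12 lists called by camera passed with an estimated correlation, the smallest such p being 0.453.

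Most calls among early response, inflammatory and acute phase genes were rises. Of 22 immediate early genes 16 rose and none fell (18 and 0 adjusted over the list alone, median 0.76, camera adjusted p = 6.69e-05, 0.557 with an estimated correlation). Btg2 rose from 45.0 ± 1.66 to 166 ± 45.2 FPKM, and Nr4a1 rose by 1.85 on the log2 scale and Maff from 25.3 ± 2.16 to 56.4 ± 14.3 FPKM. Of 27 inflammatory cytokines and NF-kB targets 14 rose and none fell (16 and 0 adjusted over the list alone, median 0.86, camera adjusted p = 9.49e-05, 0.557 with an estimated correlation). The adhesion molecule Icam1 rose from 16.8 ± 0.495 to 55.0 ± 28.2 FPKM, and Myd88, Lcn2 and Sod2 rose by 0.43, 0.39 and 0.45 on the log2 scale. The median difference from beta-Gal was 1.52 in HuR replicate 1 and 0.51 in the other two for the inflammatory list, and 1.29 and 0.56 for the early genes. Without HuR replicate 1, 21 inflammatory genes rose and 1 fell, and without beta-Gal replicate 1, 2 or 3, 7 rose. The inflammatory call also ended with fry (0.0592), and 7 rose with no filter. Of 29 acute phase genes, 21 rose and 1 fell (22 and 2 adjusted over the list alone, median 0.26, camera adjusted p = 2.33e-05, 0.557 with an estimated correlation). Saa4 rose from 42.4 ± 2.49 to 78.1 ± 5.69 FPKM, and Saa2, Apcs and Saa1 rose by 0.40, 0.45 and 0.37 on the log2 scale. Under TPM scaling 12 acute phase genes rose and 2 fell, and under quantile normalization 11 rose. Without genes beside an expressed neighbour 11 rose. The paralogs Saa1 and Saa2 could share reads.

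**Figure D2:**
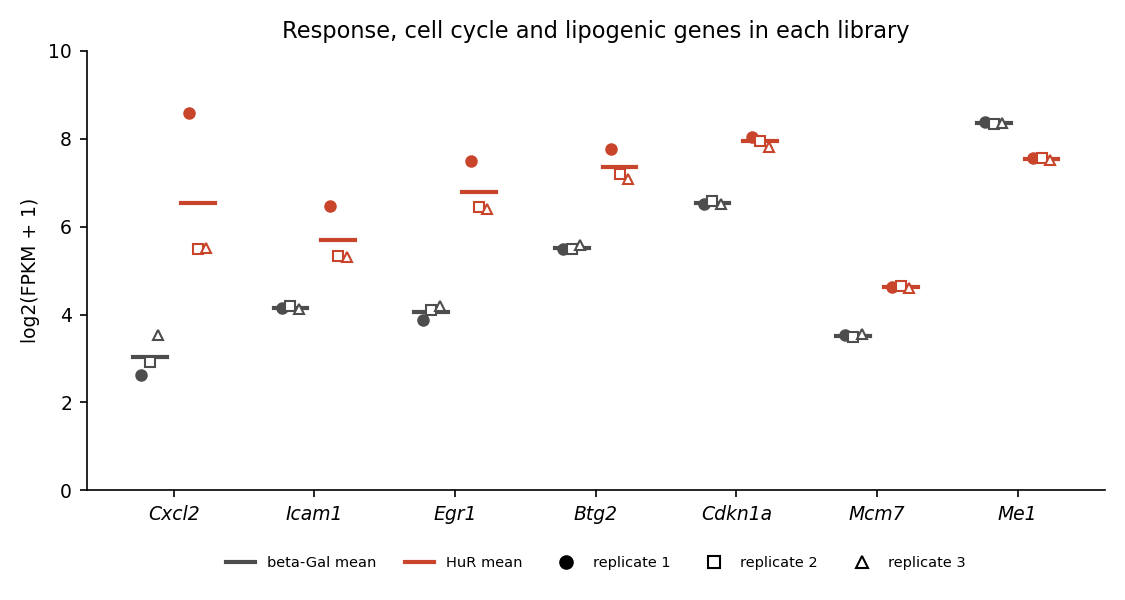
Level of 7 genes in each library on the log2(FPKM + 1) scale, with points for the 3 replicates of each group and a line for the mean. Cxcl2, Icam1, Egr1 and Btg2 are highest in HuR replicate 1 (filled red circles), while the 3 HuR libraries lie close together for Cdkn1a, Mcm7 and Me1.

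Most tested genes of the lipogenesis and bile acid lists fell. Of 26 lipogenesis and triglyceride synthesis genes, 19 fell and 1 rose (the same counts adjusted over the list alone, median -0.34, camera adjusted p = 6.07e-05, 0.463 with an estimated correlation). Malic enzyme, Me1, fell from 327 ± 5.10 to 186 ± 3.52 FPKM, and Acss2, Gpam and Elovl6 fell by 0.59, 0.86 and 0.64 on the log2 scale. Of 21 bile acid synthesis and transport genes, 13 fell and 1 rose (14 and 1 adjusted over the list alone, median -0.30, camera adjusted p = 5.91e-04, 0.453 with an estimated correlation). The bile acid receptor Nr1h4 fell by 1.33 on the log2 scale, and Baat, which conjugates bile acids, fell from 79.1 ± 1.76 to 46.0 ± 1.34. The transporters Abcb4 and Slco1a1 fell by 0.47 and 0.58 on the log2 scale. Of 37 cytochrome P450 and conjugation genes, 12 fell and 3 rose (the same counts adjusted over the list alone, median -0.13, camera adjusted p = 0.045, 0.557 with an estimated correlation). Ugt2b1, Ugt2b5, Aox3 and Cyp2c29 fell by 0.76, 0.65, 0.76 and 0.49. This last call ended without beta-Gal replicate 1 (0.0616), HuR replicate 2 (0.0756) or HuR replicate 3 (0.0645). It also ended with a pseudocount of 0.1 (0.0513), with median centring (0.0714), among protein-coding genes only (0.0772), without genes beside an expressed neighbour (0.127) and with the GC trend removed (0.403). Without beta-Gal replicate 2 or 3, 1 of these genes rose, under TPM scaling 22 fell and none rose, and with the GC trend removed 9 fell and 7 rose.

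Of 46 ribosomal protein genes, 31 rose and none fell (36 and 0 adjusted over the list alone, median 0.19, camera adjusted p = 1.02e-06, 0.557 with an estimated correlation), among them Rpl19, Rps19 and Rps15 at 0.26, 0.30 and 0.21. The count that rose was 15 under TPM scaling and 9 under quantile normalization, and 19 and 20 without beta-Gal replicates 2 and 3. Under quantile normalization the adjusted p was 0.146 for Rpl19 and 0.0749 for Rps15, and that of Rps15 was 0.0529 under TPM scaling. Of 13 mitochondrially encoded mRNAs, 10 rose and none fell (11 and 0 adjusted over the list alone, median 0.27, camera adjusted p = 0.0051, 0.463 with an estimated correlation), among them mt-Nd4l at 2.55 and mt-Cytb, mt-Co1 and mt-Nd5 at 0.32, 0.34 and 0.27. The count that rose was 1 with no filter, 4 under quantile normalization, 6 under TPM scaling and 5 with the length trend removed. This call ended under quantile normalization (0.191) and with the length trend removed (0.0545), and 6 members rose without beta-Gal replicate 1 or 3. With no filter the adjusted p of mt-Cytb, mt-Co1 and mt-Nd5 was 0.0573, 0.298 and 0.0782, and under quantile normalization mt-Cytb was at 0.0669 and mt-Co1 at 1.0. Of 51 nuclear-encoded oxidative phosphorylation genes, 13 rose and 3 fell (11 and 3 adjusted over the list alone, median 0.11, camera adjusted p = 0.018, 0.696 with an estimated correlation). Ndufb6 and Cox4i1 rose by 0.30 and 0.27, while Ndufs1 and Sdhc fell by 0.74 and 0.28. The median of this list was -0.0035 under TPM scaling, where that of all tested genes was -0.11. Its call ended under TPM scaling (0.314), under quantile normalization (0.618) and without HuR replicate 1 (0.0826). It also ended without genes beside an expressed neighbour (0.0645), with the length trend removed (0.429) and with fry (0.140). Without beta-Gal replicates 2 and 3, 5 and 6 members rose. Under TPM scaling 4 rose and 8 fell, under quantile normalization 7 rose and 7 fell, with median centring 26 rose, with the GC trend removed 21 rose, and without genes beside an expressed neighbour 7 rose. The mitochondrial share of reads was 4.69 ± 0.096% in beta-Gal and 5.61 ± 0.191% in HuR libraries (SD, n = 3 each). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 samples allow.

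**Figure D3:**
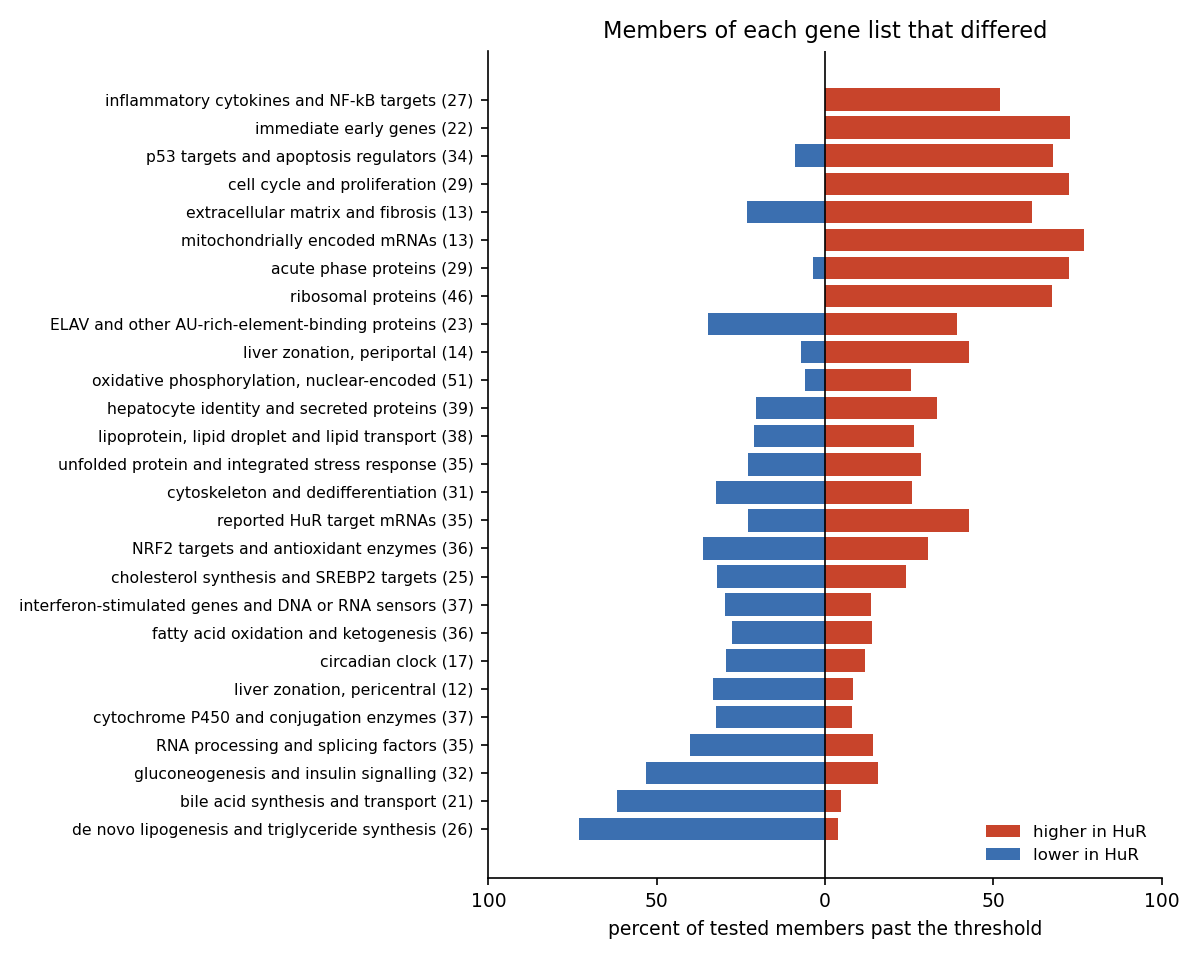
Percent of the tested members of each gene list that passed the threshold, higher in HuR to the right (red) and lower in HuR to the left (blue), with the number tested in parentheses. Lists of at least 10 tested members are shown in order of their median log2 difference, from inflammatory genes at the top to lipogenesis at the bottom.

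Messages reported in the literature as HuR targets went both ways. Of 35 tested, 15 rose and 8 fell (15 and 9 adjusted over the list alone, median 0.03, or -0.07 under TPM scaling, camera adjusted p = 0.46). Ptma rose from 231 ± 3.36 to 331 ± 11.1 FPKM, and Cdkn1a, Mdm2 and Fos rose by 1.40, 1.73 and 2.17 on the log2 scale, Fos being at 29.2 FPKM in HuR replicate 1 and 10.2 and 8.94 in the other two. Xiap, with the smallest adjusted p of the list (2.48e-05), fell by 1.13, and Actb fell by 0.44. Under TPM scaling 14 of these targets rose and 15 fell. Of 23 ELAV and other AU-rich-element-binding proteins, 9 rose and 8 fell (10 and 8 adjusted over the list alone, median 0.16, camera adjusted p = 0.638), and 5 rose without beta-Gal replicate 2 and 7 under TPM scaling. Apart from Elavl1, Hnrnpa1 rose from 54.0 ± 2.52 to 105 ± 4.99 FPKM, while Hnrnpdl fell from 36.1 ± 0.508 to 14.1 ± 1.26 and Parn, a deadenylase, fell by 0.67 on the log2 scale. Of 35 RNA processing and splicing factors, 5 rose and 14 fell (the same adjusted over the list alone, median -0.16, camera adjusted p = 0.119, 0.0359 without HuR replicate 1 and 0.00525 with no filter). With the GC trend removed this median was 0.012, with 10 higher and 10 lower. Srsf6, Srsf11 and Luc7l2 fell by 0.82, 0.94 and 0.67, and Hnrnpa2b1 rose by 0.58.

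The other metabolic lists did not pass the camera test. Of 32 gluconeogenesis and insulin signalling genes, 5 rose and 17 fell (7 and 18 adjusted over the list alone, median -0.19, adjusted p = 0.119, but 0.00574 with no filter and 0.0304 with FPKM of at least 5). Slc2a2 and Slc37a4 fell by 0.65 and 0.53 on the log2 scale, and Irs2 rose by 0.77. Of 36 fatty acid oxidation and ketogenesis genes, 5 rose and 10 fell (the same adjusted over the list alone, median -0.07, adjusted p = 0.363). Fgf21, a hepatic hormone, rose from 62.1 ± 6.13 to 258 ± 23.4 FPKM, while Hadhb and Cyp4a14 fell by 0.58 and 0.58. Of 38 lipoprotein, lipid droplet and lipid transport genes, 10 rose and 8 fell (the same adjusted over the list alone, median 0.07, or -0.04 under TPM scaling, adjusted p = 0.403). Fabp1 and Apoa4 rose by 0.31 and 0.33, and Cidec and Abcg8 fell by 0.47 and 0.68. Of 25 cholesterol synthesis genes, 6 rose and 8 fell (7 and 8 adjusted over the list alone, median -0.02, or 0.02 with median centring, adjusted p = 0.797). Idi1, Msmo1 and Sqle fell by 1.06, 0.94 and 0.54. Without beta-Gal replicate 1, 3 fatty acid oxidation genes rose and 6 fell, and without beta-Gal replicate 2 or HuR replicate 2, 3 rose. Without beta-Gal replicate 2, 5 lipoprotein genes fell, and without beta-Gal replicate 3 or HuR replicate 2, 4 fell. Without beta-Gal replicate 2 or 3, 3 cholesterol synthesis genes rose. Under TPM scaling 1 fatty acid oxidation gene rose and 19 fell, and 7 lipoprotein genes rose and 13 fell. With median centring 10 cholesterol synthesis genes rose and 8 fell, and 8 gluconeogenesis genes rose and 15 fell, or 9 and 11 with the length trend removed.

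Hepatocyte identity genes moved in both directions. Of 39 tested, 13 rose and 8 fell (14 and 8 adjusted over the list alone, median 0.07, mean -0.03, median -0.04 under TPM scaling, adjusted p = 0.363), and 7, 6 and 6 rose without beta-Gal replicates 1, 2 and 3. The balance turned to 3 higher and 11 lower under TPM scaling, 3 higher and 9 lower under quantile normalization, 5 higher and 7 lower with no filter and 7 higher and 9 lower with the length trend removed. Tat rose by 0.62, while the liver transcription factor Cebpa and the urea cycle enzyme Cps1 fell by 0.58 and 0.62. Of 14 periportal genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.13, adjusted p = 0.0728, but 0.0320 without HuR replicate 2), with Pigr, Pck1 and Gls2 higher by 0.27, 0.85 and 0.39. Of 12 pericentral genes, 1 rose and 4 fell (the same adjusted over the list alone, median -0.12, adjusted p = 0.467), the falls being those of Rnf43, Glul, Cyp1a2 and Gulo, whose groups' means were 1.29 and 0.579, 104 and 87.8, 199 and 181, and 107 and 96.9 FPKM in beta-Gal and HuR. Pericentral falls numbered 2 without beta-Gal replicate 1, 2 or 3 or HuR replicate 2, and no gene rose without beta-Gal replicate 1 or 3 or HuR replicate 3. The call of Cyp1a2 ended without any 1 library except HuR replicate 1 (adjusted p 0.0522 to 0.0757). That of Gulo ended without any beta-Gal replicate or HuR replicate 2 (0.0629 to 0.0887). Of 17 circadian clock genes, 2 rose and 5 fell (the same adjusted over the list alone, median -0.12, adjusted p = 0.28), with Clock, Nr1d2 and Hlf at log2 differences of -0.95, -0.57 and -0.83. No clock gene rose without beta-Gal replicate 1 or 2, and 1 rose without beta-Gal replicate 3 or HuR replicate 2. Under TPM scaling 7 pericentral and 10 clock genes fell.

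Stress, interferon and structural lists were mixed. Of 37 interferon-stimulated genes and nucleic acid sensors, 5 rose and 11 fell (4 and 11 adjusted over the list alone, median -0.04, or 0.003 with median centring, adjusted p = 0.363). Tap1 rose from 10.7 ± 0.292 to 19.5 ± 0.971 FPKM, while Igtp, Usp18 and Oasl1 fell by 0.55, 0.48 and 0.71. Interferon rises numbered 1 without beta-Gal replicate 1 or 2 or under TPM scaling and 3 without HuR replicate 2. Of 35 unfolded protein and integrated stress response genes, 10 rose and 8 fell (11 and 11 adjusted over the list alone, median 0.05, mean -0.04, median -0.06 under TPM scaling, adjusted p = 0.805). Manf and Pdia3 rose by 0.65 and 0.40, and Slc7a11 and Chac1 fell by 0.89 and 1.61. Under TPM scaling 6 of these rose and 14 fell, and under quantile normalization 7 rose and 12 fell. Of 36 NRF2 targets, 11 rose and 13 fell (14 and 14 adjusted over the list alone, median 0.01, mean -0.03, camera direction down, median -0.10 under TPM scaling, adjusted p = 0.926), with Me1, Ugdh and Gstm3 at -0.81, -0.62 and -0.60, and 7 rose without beta-Gal replicate 3. Under TPM scaling 6 NRF2 targets rose and 16 fell, and with median centring 16 rose and 11 fell. Of 31 cytoskeleton and dedifferentiation genes, 8 rose and 10 fell (9 and 11 adjusted over the list alone, median 0.03, mean -0.03, median -0.08 under TPM scaling, adjusted p = 0.926), with Actb, Tubb2a and Tubb2b at -0.44, -0.61 and -0.92 and Spp1 at 0.38. Without beta-Gal replicate 1, 5 of these rose and 6 fell, and without beta-Gal replicate 3, 6 fell. With median centring 11 rose and 7 fell. Of 13 extracellular matrix genes, 8 rose and 3 fell (the same adjusted over the list alone, median 0.28, adjusted p = 0.0728, but 0.0429 under TPM scaling, 0.0338 with no filter and 0.0458 with the length trend removed). Mmp14, Lamc1 and Smad7 rose by 0.67, 0.52 and 0.53 and Tgfbr1 fell by 0.32. The call of Tgfbr1 ended once the GC trend was removed (adjusted p 0.284, log2 difference -0.07).

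Summed marker levels of most other liver cell types were higher in HuR libraries. They were 23.7 ± 2.34 and 39.8 ± 2.60 FPKM for macrophages, 12.7 ± 0.107 and 17.3 ± 1.12 for endothelial cells, 3.27 ± 0.253 and 5.14 ± 0.828 for stellate cells and 161 ± 7.11 and 200 ± 9.89 for cholangiocytes (exact permutation p = 0.1 each, n = 3 each). Single genes carried most of 3 of these sums: Cd68, at 18.3 and 33.2 FPKM, that of macrophages, Ecm1, at 1.65 and 3.03, that of stellate cells, and Spp1, at 142 and 185 and also in the cytoskeleton list, that of cholangiocytes. Col3a1 and Pdgfrb, other stellate cell markers near the floor, were lower in HuR, Col3a1 at 0.0357 and 0.0129 FPKM and Pdgfrb at 0.0321 and 0.00752. Of 7 endothelial markers tested, 3 rose and none fell (the same adjusted over the list alone, median 0.27, camera adjusted p = 0.042, 0.463 with an estimated correlation, 0.0590 without HuR replicate 1). That call also ended with median centring (0.0570), quantile normalization (0.0702), voom (0.0640), the rank test (0.0529), the length (0.0540) or GC trend removed (0.0802) and without genes beside a neighbour (0.121). These were Eng, from 1.33 ± 0.156 to 2.18 ± 0.172 FPKM, Stab1 and Aqp1. The call of Aqp1 ended without any beta-Gal replicate or HuR replicate 2 (0.0741 to 0.105). Of 3 macrophage markers tested, Cd68 rose from 18.3 ± 1.63 to 33.2 ± 5.50 FPKM and the other two did not pass (the same count adjusted over the list alone, camera adjusted p = 0.285). The macrophage transcripts Lyz2, C1qa, Clec4f and Adgre1 were at 0.976, 0.242, 0.340 and 0.145 FPKM in beta-Gal and 1.27, 0.412, 0.240 and 0.212 FPKM in HuR. The single stellate cell marker tested, Ecm1, rose from 1.65 ± 0.112 to 3.03 ± 0.515 FPKM (the same adjusted over the list alone, camera adjusted p = 0.28). Of 4 cholangiocyte markers, Spp1 rose and Cldn4 fell from 13.4 ± 0.792 to 8.63 ± 1.13 FPKM (the same adjusted over the list alone, median 0.08, mean -0.01, median -0.02 under TPM scaling, camera adjusted p = 0.997). The erythroid marker Alas2 was at 10.7 ± 0.483 and 10.5 ± 0.651 FPKM and did not pass, over all genes or adjusted over the list alone (limma adjusted p = 0.752, camera adjusted p = 0.952). No lymphocyte or neutrophil marker reached the level needed for testing, and their summed FPKM was 0.276 ± 0.114 and 0.514 ± 0.112 (exact p = 0.1, n = 3 each).

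Libraries grouped by virus. The Pearson correlation of log2(FPKM + 1) over the tested genes was 0.991 between beta-Gal libraries, 0.983 to 0.990 between HuR libraries and 0.951 to 0.961 between groups. The first principal component took 69.35% of the variance and separated the groups, and the second took 12.3% and set HuR replicate 1 apart from HuR replicates 2 and 3. All 6 pairs of replicates differed by more than counting error, the only noise in that test, with a chi-square per degree of freedom of 4.78 to 19.9. This bears only on whether any library is a copy of another, not on whether cultures were separate. More gene models had a value above 0 in HuR (20096 ± 273) than in beta-Gal libraries (19402 ± 54.9), and the 10 most abundant genes took 16.7 ± 0.375% of reads in HuR and 15.03 ± 0.136% in beta-Gal (exact permutation p = 0.1 for both, n = 3 each).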

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

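The settings without genes beside an expressed neighbour and with a length or GC trend removed were chosen after seeing the data; the others were planned, and the planned raw-count alternative was not run, since the table holds FPKM. The count of genes past the threshold, 5137, ranged from 3573 (FPKM of at least 5) to 5391 (voom on recovered reads), within 1.5 times of it under every setting, and from 3931 to 5284 with 1 library left out. The higher genes numbered 1543 under TPM scaling. The number of genes at least 2-fold apart, 415 (297 higher, 118 lower), moved more. It was 730 (446 and 284) with a pseudocount of 0.1, 198 (107 higher) with FPKM of at least 5, 641 (292 lower) under TPM scaling, 776 (467 and 309) with voom, 251 (152 higher) without genes beside a neighbour and 253 (46 lower) with the GC trend removed. With a pseudocount of 0.5 the lower genes numbered 188. Smaller pseudocounts and voom shrink low genes less, and a stricter filter tests fewer. The cause of the TPM and GC shifts was not tested. With the length trend removed 52.8% of calls were higher and with the GC trend removed 52.0%, against 45.4%; median centring gave 54.7%. Camera lists numbered 12, with 0 when camera used an estimated correlation, 23 under fry, which asks another question, and 8 to 15 under the remaining settings. For the bile acid list the estimated correlation was -0.0098, below the preset 0.01. Its unadjusted camera p still went from 1.48e-04 to 0.0142, so a larger correlation does not account for that loss. For the other called lists, whose estimates were above the preset, the cause was not tested. The estimated correlation rests on only 4 residual degrees of freedom. The absence of calls there therefore does not show that these lists did not shift. Elavl1 stayed past the threshold under every setting, at log2 differences of 7.98 to 8.39. The rise in the mitochondrial share, 0.914 percentage points of reads, was 1.33 points under TPM scaling.

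No pairing of samples by replicate number was detected, which does not show that they were unpaired. Deviations of same-numbered samples correlated at -0.029, 0.00067 and -0.014, and no beta-Gal sample correlated best with the HuR sample of its own number. With the replicate block 4549 genes passed. Of 171 named genes refitted, 33 changed their side of the threshold under at least 1 setting and none reversed. Among all called genes some log2 differences changed sign. These numbered 89 of 4678 with the GC trend removed and 23 of 5137 under quantile normalization. They numbered 3 with the length trend removed and 2 under TPM scaling. For the 12 called lists, 38 refits lost the call and 260 kept it. In the simulation, where 10854 of 11044 genes were unchanged, 23.4% of the smallest changes were recovered. The rate may differ for the real comparison, where many more genes pass.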

Other observations

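The tests of the Smoc2 explanations and of macrophages in HuR replicate 1, the use of Cd68 and the sum of all listed macrophage markers beside the 6 transcripts, and the settings that remove a length or GC trend, were chosen after the results had been seen, and the genes in the next paragraph after their values had been seen.

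Beyond mRNA, the 7SK RNA, Rn7sk, a small nuclear RNA that holds back the elongation factor P-TEFb, rose from 11.05 ± 0.630 FPKM in beta-Gal to 421 ± 11.6 FPKM in HuR (SD, n = 3 each, limma log2 difference 5.13, adjusted p = 2.74e-08). It is 1 of 4 genes more than 4 apart on the log2 scale, with Elavl1, Smoc2 and Mup10. The noncoding gene Gm26917 rose from 24.0 ± 1.94 to 302 ± 23.9 FPKM. How rRNA was removed or mRNA selected is not given, and whether that step bears on the levels of Rn7sk and Gm26917 was not tested. Other noncoding RNAs moved less: Snora31 rose by 1.31 and Snora17 fell by 1.32, the nuclear RNA Malat1 fell by 0.51, and the mitochondrial rRNAs mt-Rnr1 and mt-Rnr2 rose by 0.36 and 0.29, calls that ended under quantile normalization (0.154 and 0.155). Mup10, of the multigene major urinary protein family, was at 668 and 817 FPKM in beta-Gal replicates 1 and 2, 1.56 in beta-Gal replicate 3 and 0.69 to 1.38 in HuR libraries. It did not pass (adjusted p = 0.064, 3.22e-05 without beta-Gal replicate 3, range over all settings 3.22e-05 to 0.594), and reads shared between its paralogs leave its level uncertain.

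Many genes that are nearly silent in beta-Gal rose in HuR beside an active neighbour. Of 94 protein-coding genes under 1 FPKM in beta-Gal and at least 2-fold higher in HuR, 47 (50%) start within 10 kb of the end of an expressed same-strand gene. The share was 8.72% of 4073 protein-coding genes not called higher, within the same range of mean FPKM (exact one-sided p = 3.7e-24). That comparison set was not matched on the beta-Gal level, and genes are not independent replicates. Upstream genes on the opposite strand were no more frequent (7.45 against 9.50%). Among low genes chosen by mean level alone, the median log2 difference (pseudocount 0.1) was 0.51 after a same-strand neighbour (453 genes), 0.37 beside a facing gene (421) and 0.014 with no expressed gene within 10 kb (2688). It went from 0.99 at gaps up to 1 kb to 0.095 at 50 to 100 kb. DNA spread evenly over the HuR libraries would raise isolated genes as well. The difference of 0.495 between the first and last class argues against it (permutation p = 1e-04, the smallest possible, across genes). Unspliced RNA was part of the same prediction. It comes from transcribed regions and need not raise isolated genes, so this comparison cannot weigh it. A candidate explanation is transcription past gene ends in HuR samples. Whether it came from HuR or from another difference between the cultures was not tested.

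Smoc2 went from 1105 FPKM to 3 reads. Fibroblasts or stellate cells in the beta-Gal cultures would bring their collagens, but 7 fibroblast transcripts summed to 0.429 FPKM there. Misplaced reads of the paralog Smoc1 are argued against by HuR libraries with at least 19.4 FPKM of Smoc1 and at most 2 Smoc2 reads each. A Smoc2 sequence introduced in the beta-Gal cultures only cannot be told apart from a loss of the message in HuR samples: Smoc2 is the 1 gene over 100 FPKM in 1 group and under 0.1 in the other, and the table carries no reads per position.

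Inflammatory and early response genes were highest in HuR replicate 1. Macrophages in that sample cannot be told apart, as their markers went both ways: the sum of Lyz2, Cd74, C1qa, C1qb, Clec4f and Adgre1, genes near the floor, was 2.11 FPKM there against 6.07 and 4.07 in the other HuR libraries, which by itself meets the value set against macrophages, while Cd68 was at 39.5 against 30.5 and 29.5. Elavl1 was 1.44 times as high there as in the mean of the others. A larger overall response to more HuR cannot be told apart: other called genes differed from beta-Gal by a median of 1.04 times as much as in replicates 2 and 3 (quartiles 0.82 and 1.34), between the values set in advance for and against it, with 1.125 for genes called higher, past the first value, and 0.988 for genes called lower, past the second. Other explanations were not tested, and the labels name no difference between these replicates.

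The log2 difference went with gene length (Spearman rho -0.235 across genes) and transcript GC content (0.332), and genes are not independent replicates. After removal of a length trend 85.5% of calls, and after removal of a GC trend 84.7% of those with a GC value, stayed past the threshold in the same direction, which argues against either trend as the whole cause. Single beta-Gal libraries also varied with GC, at -0.14 to 0.21.

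The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 5137 genes and the highest of the others 1, so 1 split of the 10 gave as many.

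The hypothesis that AU-rich or U-rich elements in 3' UTRs go with higher levels in HuR libraries was not borne out by the plain correlations across 9320 genes. The density of ATTTA per kb correlated with the log2 difference at a Spearman rho of -0.165 and that of TTTTTTT at -0.108 (permutation p = 1e-04 each, the smallest possible, across genes, which are not independent replicates). With 3' UTR length, GC content and transcript length held, the sign turned and the partial correlations were 0.021 and 0.044. No p-value was computed for these, so the direction of any link depends on what is held.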
